A study of Drosophila melanogaster with 2 samples.

How the data were processed

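Binding of pan, the fly TCF and the DNA-binding effector of Wingless (Wnt) signalling, was measured by chromatin immunoprecipitation and sequencing with an antibody against GFP. The flies carried pan fused to enhanced GFP, and the material was whole Drosophila melanogaster embryos aged 0 to 24 h. There was 1 group with 2 replicates, numbered by the labels. A control is named in the descriptions of the files; it was not used here.

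The deposited files were peak lists on the dm6 assembly, per the file headers. For each replicate, and for the replicates pooled, the authors supplied a ranked list and a shorter list that passed a threshold on the irreproducible discovery rate (IDR), which scores how well peaks recur at the same rank. A conservative pooled list and a longer pooled list were both supplied. Each peak carried a score, a signal value, a −log10 q and a summit position from the authors, and the ranked lists also carried a −log10 global IDR. The deposited score was the IDR rescaled and capped, to within 1 unit in all 4 ranked lists. The scale of the authors' signal was not given in the sources used here, nor were the aligner and the peak caller, so signal was used to describe and rank peaks within a list. Read depth is unknown from these files, and no interval below covers sequencing depth. The passing lists also derived from a further file that the headers leave undescribed.

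The 6359 conservative peaks on chromosomes 2L, 2R, 3L, 3R, 4, X and Y were analysed; 7 on unplaced scaffolds were left out. The background was the 113608 pooled ranked peaks that fell short of the IDR threshold and overlapped no passing list. Positions were read from the Ensembl annotation of the same assembly. A summit within 1 kb of any transcription start site (TSS) was called a promoter summit, and the remaining summits were intergenic, intronic or exonic. Shares were compared by Fisher's exact test, two-sided, with an odds ratio and its 95% interval by the Woolf method; intervals of single shares were exact (Clopper-Pearson). Families of tests were adjusted by the Benjamini-Hochberg method. Peaks are not independent replicates, so these tests describe the list and not the spread between embryos.

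Motifs were sought on both strands within 50 bp of the summit and in 2 windows of 101 bp centred 500 bp to either side. Fisher's exact test took summit and flank windows as independent, so the pairing of each summit with its own flanks was not used. A further background of 11827 ranked peaks was matched on GC content and TSS class, 891 fewer than sought. The odds ratio of the TCF core was ranked among 419 permutations of its letters. All 2080 distinct 6-mers were tested the same way. For gene lists, the share of genes with a summit in the gene body or 2 kb either side was set against 10000 random lists matched on gene length in 20 bins, drawn from 12520 protein-coding genes with a ranked peak in the same territory. The relation of motif to signal was tested with 100000 permutations. Replicate peaks were called shared when they overlapped by 50% of the shorter peak, and chance came from 1000 random placements.

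The lists comprised Wnt pathway components, reported Wingless-responsive genes, Hox, gap, pair-rule and segment polarity genes, regulators of mesoderm and heart, nervous system, endoderm and gut, and trachea and epidermis, the Notch, BMP and Hedgehog pathways, hemocyte and germline markers, muscle structural genes, cytosolic ribosomal protein genes, proteasome genes, odorant and gustatory receptors, Jonah and trypsin proteases, and chorion and yolk genes. For 3 members the annotation uses a newer symbol (hry, Delta and nanos), matched through RefSeq synonyms. Lists, motifs, tests and alternatives, with the permutation ranking and the matched background among them, were fixed before the data were examined, apart from those named below as added. The genes named were pan, those nearest the 20 strongest peaks, every Wnt or Wingless-responsive gene with a summit within 1 kb of a TSS, with values for the 10 of strongest peak, the 10 genes with the most summits, and up to 3 members of each other list with the strongest peak. The genes named at peaks left out of the conservative list were outside this rule and chosen after their values were seen. A gene that this rule names is not reported here.

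Alternatives covered the longer pooled list, each replicate's own list, merged overlapping peaks, other windows, backgrounds, motif forms and overlap rules. A stricter IDR of 0.01 removed 0 peaks, because every conservative peak already passed it. The stronger part of the list by signal, and the restoration of 151 passing peaks left out of the conservative list, were added after seeing the data. So were the draws from the ranked list of replicate 2, the comparison of coding exons, the shares within 100 bp of a TSS, the positions of GAGA sites, the naming of CTTTGA and ACAAAG, and the comparisons of the TCF core in flanks by position class and by signal, where the ratios of odds ratios carried a normal interval on the log scale.

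The procedures were tested on simulated data. With the motif planted in 5% of 6000 windows, the odds ratio was 2.02 against 2.04 expected. The simulated summit and flank windows had the same base frequencies, so the effect of base composition was not tested. Of 400 random length-biased lists of 30 genes, 2.5% passed an unadjusted 0.05, and 82% of lists with added hits passed. Most lists tested below were smaller and their p-values were adjusted, so the 82% does not carry over to them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.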

Results

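In whole embryos of 0 to 24 h, 6366 conservative peaks were listed for pan fused to enhanced GFP, of which 6359 lay on the main chromosome arms. The control was not used here, so whether the peaks are specific to pan was not tested against it. Below, bound and binding refer to such peaks. Replicate 1 alone gave 4557 peaks and replicate 2 alone 5356. The longer pooled list held 7084. With 1 group and no second condition, the comparisons are between the replicates and between bound sites and the genome around them.

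The same promoters led both replicates. The strongest pooled peak, at X 2703702 to 2704049 and 23 bp from a TSS of Ugalt, a UDP-galactose transporter, had a signal of 1467.7 in replicate 1 and 1478.6 in replicate 2 and ranked 1 in each. The next, at 3L 19590462 to 19590779 and 95 bp from a TSS of CG14100, had 1378.4 and 1278 and ranked 2 in each. Of the replicate 1 peaks, 75.3% (95% interval 74 to 76.5%, 3425 of 4549) were shared with replicate 2, and 64% of the replicate 2 peaks were shared with replicate 1. Random placement gave 1.29% on average and at most 1.78% in 1000 draws, and 100 random draws from the ranked list of replicate 2, a check added after seeing the data, gave 4.85% on average and at most 5.72%. Over the shared peaks the signals had a Spearman rho of 0.791 (95% interval 0.777 to 0.803), which is across peaks that are not independent. Both passing lists of the replicates held 53% of the conservative peaks, and neither held 20.9%.

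**Figure D1:**
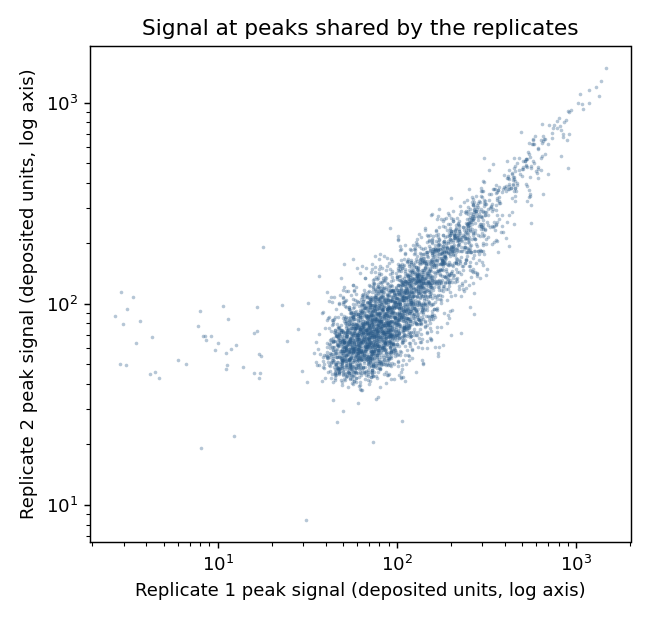
Signal of each peak shared by the replicates, replicate 1 on the horizontal axis and replicate 2 on the vertical axis, both log scaled in the deposited units; each point is 1 of 3425 replicate 1 peaks. Strong peaks lie near a line, with a Spearman rho of 0.791, and a few points have a low signal in replicate 1 alone. Each replicate 1 peak was paired with the strongest replicate 2 peak that overlapped it. Points low in replicate 1 alone can therefore come from the pairing.

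Binding was enriched at promoters. Of the conservative summits, 53.9% (95% interval 52.7 to 55.1%, 3428 of 6359) were within 1 kb of a TSS, against 27% of the background peaks, an odds ratio of 3.16 (95% interval 3 to 3.33). Within 100 bp of a TSS the shares were 18.3% and 3.85%. Coding exons held 0.44% of summits and 16.8% of background peaks, an odds ratio of 0.0219 (0.0151 to 0.0318). It was 0.038 against uniform positions, 0.0131 in the list of replicate 1 alone and 0.00625 in the stronger peaks by signal. Intergenic summits were fewer than in the background, 12% against 18.9%, with an odds ratio of 0.585 (0.541 to 0.631) and a Fisher's exact p of 1.29e-47. Introns held 32.2% and 34.3%, an odds ratio of 0.908 (0.861 to 0.959) with a Fisher's exact p of 0.000482. With a TSS window of 500 bp the intron odds ratio was 1.05 and its p 0.0524, so the intron difference depended on the window. With that window 43.4% of summits and 14.9% of background peaks were at promoters, an odds ratio of 4.39.

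**Figure D2:**
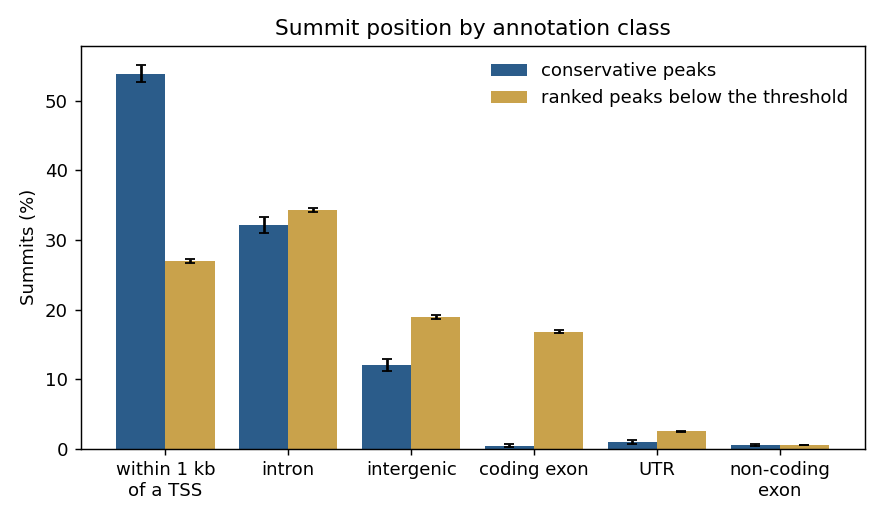
Percentage of summits in each annotation class for the 6359 conservative peaks and the 113608 ranked peaks below the threshold; bars are shares and whiskers exact 95% intervals. The promoter class holds 53.9% of conservative summits and 27% of the background.

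Of the 20 strongest peaks, 17 had a summit within 1 kb of a TSS of some gene, 2 were intronic and 1 was intergenic. After Ugalt and CG14100 came CG11050, whose peak lay in its intron with a pooled signal of 2509.3, mRpL41, which encodes a mitochondrial ribosomal protein, with 2423, and CG7601 with 2251.3. Tcs5, CenG1A, Art3, the Polycomb group gene ph-p and PNPase followed, with signals from 2149.7 to 2009.4. CG18549, CG13323, eIF6, CG5611 and Fkbp14 ranged from 1854.5 to 1653.2, and tara, Chro, CG32772, px and gish from 1644.7 to 1550.8. The CG13323 peak was intergenic, 11911 bp from its TSS. Every one of the 20 peaks was in both replicates' passing lists, an outcome that their choice by pooled signal favours.

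The genes with the most summits spanned 48.4 to 394 kb. The cell adhesion gene kirre held 28 and CG1677 held 22. The co-repressor gene sbb held 17, the BMP pathway gene shn and the kinase gene Tlk 16 each, and the homeobox gene hth and the overlapping genes Glut4EF and CG46467 14 each. The nuclear receptor gene ftz-f1 and the kinase gene Raf held 13 each.

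Peaks per Mb were similar on the large arms, from 45 on 2R to 50.5 on 2L. Relative to the background, 3L had an odds ratio of 1.15 (adjusted p = 2.31e-05, Fisher's exact test over 7 arms) and 2L of 1.1 (adjusted p = 0.00589). By the same exact test 3R was lower, at 0.915 (adjusted p = 0.00589), as was X, at 0.923 (adjusted p = 0.0216), which stood at 0.996 in the list of replicate 1 alone and at 0.986 in the stronger peaks by signal. The call on 3R was lost, at 0.966 (adjusted p = 0.249, exact test), when the 151 passing peaks absent from the conservative list were restored, of which 99 lay on 3R, and 2R then passed as lower, at 0.931 (adjusted p = 0.0446, exact test). Chromosome 4 held 6 conservative peaks and 66 background peaks, an odds ratio of 1.62 with an adjusted p of 0.282. It was 5.16 in the list of replicate 2 alone and 3.17 in the longer pooled list, and passed in both (Fisher's exact adjusted p = 4.7e-06 and 0.00153). Chromosome Y held 0 conservative and 271 background peaks.

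Wnt pathway genes were bound at 26 of 34 tested members (76.5%), against 61.3% in length-matched lists, a ratio of 1.25 with an adjusted permutation p of 0.366. Reported Wingless-responsive genes were bound at 14 of 23 members, against 14.2 expected (ratio 0.987, adjusted permutation p = 1). Without length matching the Wnt ratio was 1.73, with an adjusted permutation p of 0.0014. Within 1 kb of a TSS, a summit lay at 18 of 34 tested Wnt genes against 14.2 expected (adjusted permutation p = 0.545). For Wingless-responsive genes it was 8 of 23 against 9.6 expected (adjusted permutation p = 0.86). Across both lists 23 of 54 genes had a summit within 1 kb of a TSS. The kinase gene gish had the strongest, with 826.5 in replicate 1 and 735 in replicate 2. The co-repressor gene gro had 365.6 and 367.5, the kinase gene sgg 301.8 and 285.9, the feedback antagonist gene nkd 193.7 and 283.8, and nej, which encodes the CBP acetyltransferase, 200.4 and 267.7. The others were Dll (pooled signal 264.6), CtBP (196.8), wls (170.2), wg (165.9) and Apc2 (161.9). The nkd locus held 10 summits, of which 1 was within 1 kb of a TSS. The remaining 13 were dally, Wnt6, slp2, Apc, pxb, vg, fz3, dlp, slmb, Axn, hth, Wnt4 and hyx. For vg, slmb, Axn, Wnt4 and hyx the peak near the TSS was in neither replicate's passing list. The Wnt list gene nmo was not counted, but a passing peak 83 bp from its TSS (signal 93.2) was among those left out of the conservative list. The pan gene itself, at chromosome 4 from 69326 to 114270, held 0 conservative summits. The gene and 2 kb either side held 0 peaks even in the pooled ranked lists, so pan was not among the 34 tested members. Background peaks were sparse on chromosome 4, at 49 per Mb against 791 to 945 on the large arms. The absence therefore cannot be read as a lack of binding.

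Cytosolic ribosomal protein genes held a summit more often than genes matched on length alone. With other traits unmatched, neither this excess nor the deficits given after it are shown to be specific to pan. A summit lay at 71 of 80 (88.8%) against 35.2%, a ratio of 2.52 with an adjusted permutation p of 0.0021, which rests on the smallest p the permutations can give. Among them were RpS27 (pooled signal 582.3), with a summit 9 bp from its TSS, and RpL3 (809.6), whose peak lay 4774 bp from its own TSS and within 1 kb of that of another gene. Odorant and gustatory receptor genes were bound less often, at 13 of 100 against 38.1 expected (ratio 0.341, adjusted permutation p = 0.0021), led by Or85f (544.8, but 3210 bp from its own TSS and within 1 kb of another), Or88a (337.1) and Gr89a (298.8). The ratio was 0.204 in the list of replicate 2 alone and 0.132 with summits near a TSS. Neural regulators were bound at 2 of 16 against 8.43 expected (ratio 0.237, adjusted permutation p = 0.007), namely elav (794) and sim (144.5). The ratio stayed below 1 but did not pass in the list of replicate 1 alone, at 0.422 (adjusted permutation p = 0.269), in that of replicate 2 alone, at 0.512 (0.227), or in the longer pooled list, at 0.449 (0.084). Nor did it pass in the stronger peaks by signal, at 0.333 (adjusted permutation p = 0.167), with summits near a TSS, at 0.183 (0.141), or without length matching, at 0.283 (0.058).

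The other lists did not pass the adjusted threshold. Ratios above 1 were seen for proteasome genes at 1.38 (Rpn5, Rpn3, Prosalpha4), mesoderm and heart regulators at 1.19 (Mef2, tin, tup), the Notch pathway at 1.18 (E(spl)m8-HLH, neur, N), germline markers at 1.15 (ovo, piwi, gcl), the BMP pathway at 1.14 (gbb, Med, shn) and the Hedgehog pathway at 1.02 (rdx, ihog, ptc). Ratios below 1 were seen for endoderm and gut regulators at 0.849 (bin, dve, cad), pair-rule genes at 0.848 (hry, slp2, drm; 0.517 in the list of replicate 1 alone), tracheal and epidermal regulators at 0.777 (trh, rib, ovo), segment polarity genes at 0.738 (inv, wg, ptc; 1.2 in the list of replicate 2 alone), muscle structural genes at 0.714 (sls, Zasp52, Mlc2) and Hox genes at 0.696 (Antp, Abd-B, Ubx). Hemocyte markers stood at 0.632 (ush, srp, Hml), gap genes at 0.45 (knrl, hb; 0.27 in the list of replicate 1 alone and 0.24 in that of replicate 2), chorion and yolk genes at 0.393 (Yp3; 0 of 7 bound in the list of replicate 2 alone) and Jonah and trypsin proteases at 0.163 (iotaTry, adjusted permutation p = 0.0609). With summits within 1 kb of a TSS the ratio was 0.312 for Hox genes, 0.462 for tracheal and epidermal regulators and 1.79 for the Notch pathway. In the stronger peaks by signal it was 0.22 for hemocyte markers and 0.61 for the Hedgehog pathway. None of these passed the adjusted threshold. The Jonah and trypsin list had 0 of 20 genes bound in each replicate's own list. It passed in the longer pooled list (adjusted permutation p = 0.0476), in replicate 2 alone (0.0252), without length matching (0.0021) and with all protein-coding genes as background (0.042). A territory can take in a neighbour's promoter, and gbb and eIF6 shared 1 peak, as did gro and E(spl)m8-HLH. The named peaks of Mef2, tup, E(spl)m8-HLH, gbb, Med, ihog, Mlc2, Rpn5, Prosalpha4, iotaTry and Yp3 lay within 1 kb of a TSS of another gene and 1046 to 23481 bp from their own.

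**Figure D3:**
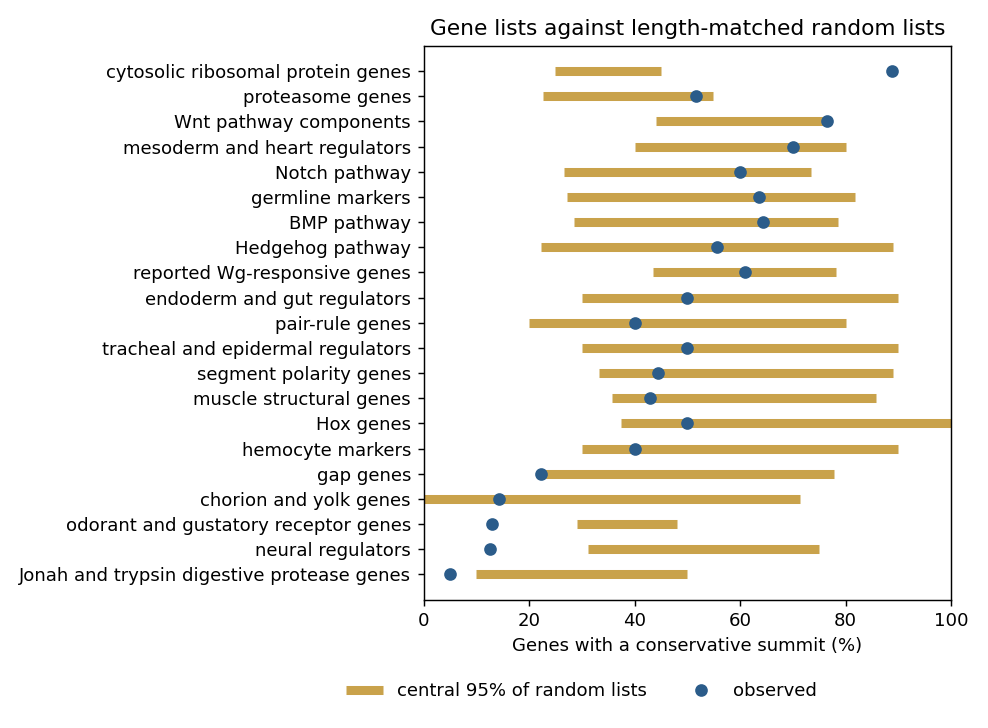
Percentage of each list's tested genes with a conservative summit in the gene body or 2 kb either side (points), with the central 95% of 10000 length-matched random lists (bars). Ribosomal protein genes lie above the bar at 88.8%, and odorant and gustatory receptor genes below it at 13%.

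The TCF core, CTTTGWW, the sequence read by the HMG box of pan, was present within 50 bp of 9.47% of summits (602 of 6359) and in 7.64% of flanking windows. The odds ratio was 1.26 (95% interval 1.14 to 1.41, Fisher's exact p = 1.93e-05). Among 419 permutations of its letters 74 had an odds ratio as high, which put the TCF core at percentile 82.3. The GC content was 35.9% at summits and 42.7% in the flanks, and the median permuted odds ratio was 1.11. Against ranked peaks matched on GC content and TSS class the odds ratio of the core was 1.12 (Fisher's exact p = 0.0431, adjusted p = 0.121), which did not pass over the 14 motifs, nor did the core in replicate 2 alone, at 1.14 (adjusted p = 0.0524). Of the 6-mers at its start, tested by Fisher's exact test, CTTTGA had an odds ratio of 1.16 (adjusted p = 0.0302), while ACAAAG, the reverse complement of CTTTGT, had 0.895 (6.6% of summits and 7.32% of flanks, adjusted p = 0.0967). The extended TCF form had an odds ratio of 1.2 (0.938 to 1.53) and passed in the longer pooled list, at 1.37 (Fisher's exact adjusted p = 0.0159).

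**Figure D4:**
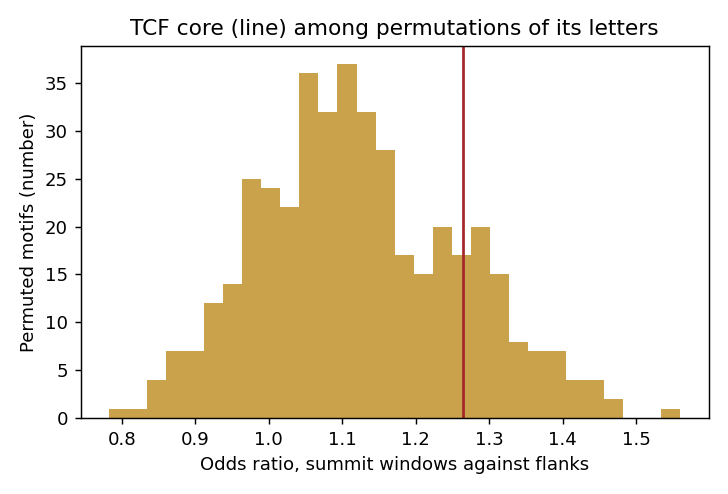
Odds ratios of the 419 permutations of the TCF core, summit windows against flanks, as a histogram, with the TCF core as a vertical line at 1.26. There are 74 permutations at or above the line.

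The site of DREF, a factor of replication-related promoters, was the most enriched of the 14 motifs, at 1.54% of summits and 0.338% of flanks, an odds ratio of 4.61 (3.22 to 6.61) with an adjusted p of 2.22e-17. It was 3.07 against the matched peaks. These were matched on the 1 kb TSS class and not on distance within it. Of summits 18.3% lay within 100 bp of a TSS, against 3.85% of all background peaks, so closeness to a TSS was not controlled. Homeodomain (1.43) and GATA (1.29) sites were also enriched over flanks, but neither passed against matched peaks, at 0.92 for homeodomain and 1.1 for GATA sites (Fisher's exact adjusted p = 0.222 and 0.0518). Depleted over flanks were the CACGTG E-box (0.496), Zelda (0.553), CA repeat (0.595), helper site (0.611), GAGA (0.67) and E-box (0.773) motifs. Against matched peaks none of these 6 was depleted past the adjusted threshold, with Zelda at 0.995, CA repeat at 0.912 and CACGTG at 0.693. The Zelda odds ratio was 0.73 in the longer pooled list and 0.729 in replicate 2 alone, and 0.522 from fewer windows in the stronger peaks by signal, none past the threshold (Fisher's exact adjusted p = 0.183, 0.292 and 0.0727). The E-box did not pass in replicate 2 alone, at 0.907. CA repeat was 0.389 in the stronger peaks and the helper site 0.406 in replicate 1 alone. In bins of 25 bp GAGA density ran from 0.308 to 0.415 sites per kb within 50 bp of the summit, reached 0.994 between 100 and 150 bp before it and 0.969 between 100 and 150 bp after it, and ran from 0.22 to 0.698 between 500 and 1000 bp away, a range that takes in the values at the centre. GAGA sites were enriched against matched peaks, at 2.03. Against flanks they stood at 0.269 in the stronger peaks by signal and 0.408 in replicate 1 alone, and did not pass in the longer pooled list, at 0.86, or in replicate 2 alone, at 1.00. Sox (0.855), Grainyhead (0.723) and AP-1 (1.05) sites did not pass, but Grainyhead sites were depleted in each replicate's own list, at 0.477 in replicate 1 and 0.406 in replicate 2 (Fisher's exact adjusted p = 0.0306 and 0.012). Of 2080 6-mers, 477 were enriched and 999 depleted. Among those present at 2% or more of summits, the 10 most enriched were ATATTA (2.42), TTTAAA (2.41), TTAAAA (2.35), TATTAA (2.3), AATATA (2.26), ATACTA (2.25), AATATT (2.22), AAATAT (2.21), CTTATA (2.2) and TACTAA (2.19), given as odds ratios.

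**Figure D5:**
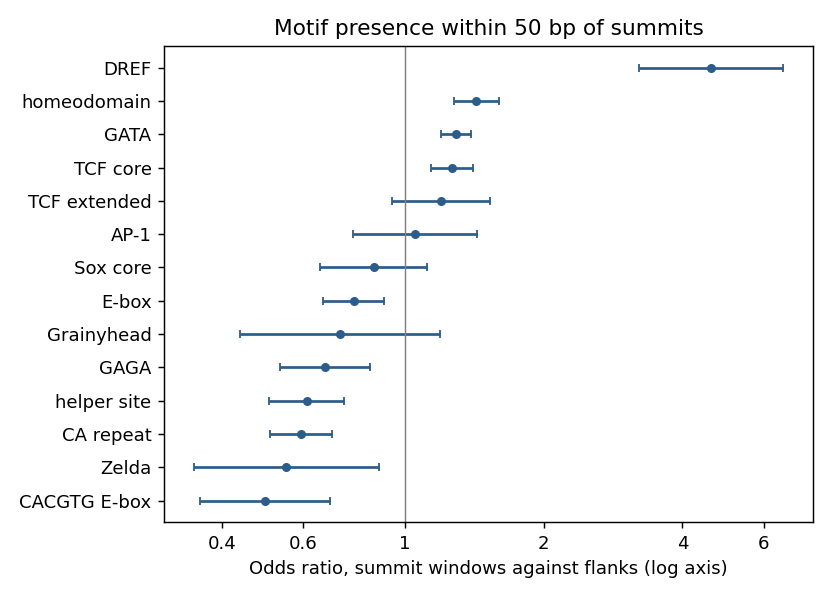
Odds ratio of motif presence within 50 bp of 6359 summits against flanking windows for 14 motifs, on a log axis; whiskers are 95% intervals. DREF stands at 4.61 and the TCF core at 1.26.

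The TCF core was less frequent at promoters than elsewhere, at 8.14% of 3428 promoter summits and 11% of 2931 other summits, an odds ratio of 0.715 (0.605 to 0.847, Fisher's exact p = 0.000107). The flanks differed in the same way, 6.71% against 8.73% (odds ratio 0.752, 0.659 to 0.857), and the enrichment over flanks was 1.23 at promoters and 1.29 elsewhere, a ratio of 0.952 (0.769 to 1.18), a comparison added after seeing the data. Its frequency at summits showed no trend with the strength of the peak. By quintile of signal, from weakest to strongest, the shares were 8.73%, 9.83%, 9.75%, 9.59% and 9.43%, with a Spearman rho of 0.00748 across peaks (permutation p = 0.548). The enrichment over flanks was higher in the stronger peaks, a comparison added after seeing the data. It was 1.48 (1.27 to 1.72, 9.91% against 6.93%) in the 3180 stronger peaks and 1.09 (0.937 to 1.27, 9.03% against 8.35%) in the 3179 weaker ones, a ratio of 1.36 (1.09 to 1.68). The flanks differed between these sets (odds ratio 0.818, 0.717 to 0.932), while the summits differed by 1.11 (0.937 to 1.31). Among the 419 permutations 31 were as high in the stronger peaks and 156 in the weaker. The median permuted odds ratio was 1.17 in the stronger peaks and 1.05 in the weaker ones, so the permuted motifs also stood higher in the stronger peaks.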

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

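The tests in this part were chosen after the left-out peaks had been seen; related counts were known before the test of fixed regions, and the outcome for repeated sequence was stated before its value was known.

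The pooled ranked list held 151 peaks on the main arms that passed the IDR threshold and were absent from the conservative list. Among the comparisons above they entered only those with restored peaks. They included the peaks near cbt (signal 2443, 2L 480916 to 481267), Lk6 (1752.7), CG18428 (1168.2), larp (1147.2) and trx (1094.5), and the cbt peak would have ranked 4. Of the 151, 99 lay on 3R and 37 on 2L. Passing peaks of the replicates that overlapped them were also left out of the replicates' own lists in 100% of cases (203 of 203), in line with the authors' filtering of fixed regions. Repeated sequence is argued against as the whole cause, since most bases were soft-masked in 4.64% of the left-out peaks. The share was 2.36% in kept peaks, an odds ratio of 2.01 (0.926 to 4.37, Fisher's exact p = 0.096), so a part played by repeats stays open. No biological explanation was tested.

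At pan itself, replicate 2 alone had a passing peak at chromosome 4, 68570 to 68859, with a signal of 51.9 and 611 bp from the gene start, while the list of replicate 1 and both pooled lists had 0 peaks in the same territory.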

How the results depend on the processing

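The stronger part of the list by signal and the restored peaks were chosen after seeing the data. Of 452 comparisons with an alternative, 381 were labelled as unchanged. These kept their direction and side of the threshold, stayed within their interval or, for counts of calls, stayed of similar size. A count could do so while its members changed. Of the 452, 50 used the IDR of 0.01, which removes 0 peaks and so says nothing about stability. Promoter odds ratios ranged from 3.15 to 4.39 and intergenic from 0.379 to 0.642. For changes below, the cause was not tested. The share of replicate 1 peaks found in replicate 2 was 78% with 1 bp of overlap, 72.9% with summits within 100 bp and 72% with equal numbers of top peaks, and rho was 0.77 with 1 bp. The intron odds ratio was 1.05 with the 500 bp TSS window. Arm 3R lost its call with restored peaks, at 0.966. The TCF core lost significance in its extended form, at 1.2, and by adjusted p in replicate 2 alone and against matched peaks, and the promoter difference of the core in the stronger peaks by signal, at 0.805. The rho of motif with signal was -0.0168 in the stronger peaks, -0.0151 with the 100 bp window and -0.0194 with the extended motif. Without either replicate in turn it ranged from -0.00236 to 0.0174, the Wingless-responsive ratio from 0.925 to 1.2, arm 2R from 0.923 to 1.04, GAGA from 0.408 to 1.00, AP-1 from 0.853 to 0.933, segment polarity from 0.916 to 1.2, mesoderm from 0.974 to 1.11, endoderm from 0.911 to 1.02 and germline from 0.995 to 1.42. With matched peaks as background the helper site was 1.1, GAGA 2.03, homeodomain 0.92, Grainyhead 1.22 and E-box 1.16. With the longer pooled list AP-1 was 0.898, the Wingless-responsive ratio 1.01 and the tracheal ratio 1.04. In the stronger peaks AP-1 was 0.837, the Wingless-responsive ratio 1.01, Hedgehog 0.61 and germline 0.965. With summits within 1 kb of a TSS mesoderm was 0.75, BMP 0.925 and Hedgehog 0.569. Without length matching the Wnt ratio passed at 1.73, and the others were Wingless-responsive 1.37, Hox 1.13, segment polarity 1.00, endoderm 1.13 and tracheal 1.13. With all protein-coding genes as background the Wingless-responsive ratio was 1.04 and Hedgehog 0.947. Depth limits are unknown, since the files give no read counts.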

Other observations

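The test that reads the share of permutations as base composition was chosen after the result was seen, although the ranking itself was fixed earlier, and the comparison of low-signal peaks with any neighbour was also chosen later; the outcomes of the others were stated before their values were known.

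DREF sites went with promoters. They lay within 50 bp of 94 of 3428 promoter summits (2.74%) and 4 of 2931 other summits (0.136%), an odds ratio of 20.6 (7.58 to 56.2, Fisher's exact p = 1.01e-20). Flanks and background peaks were not compared by position class, so the difference is not shown to be particular to the conservative peaks. No biological explanation was tested.

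The TCF core enrichment may come from the base composition of summits, since 17.7% of the permuted motifs reached its odds ratio. A hypothesis that promoter peaks mask a stronger enrichment elsewhere did not meet its stated outcome. Among the 2931 peaks away from a TSS the odds ratio was 1.29, and 21.5% of permutations reached it. The ratio of the enrichment at promoters to that elsewhere was 0.952. Its interval of 0.769 to 1.18 leaves a somewhat stronger enrichment elsewhere open. Peaks at Wnt pathway and Wingless-responsive genes held the core in 15 of 121 cases (12.4%) against 9.41% of other peaks, an odds ratio of 1.36 whose interval of 0.788 to 2.35 leaves the question open. Helper sites within 100 bp, thought to aid TCF binding, were present in 5.32% of peaks with a core and 4.86% of those without, an odds ratio of 1.1 (0.754 to 1.6), also open.

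A set of 294 conservative peaks had a pooled signal under 50, and 97.3% of them lay within 500 bp of another summit, against 7.98% of other peaks. Whether the replicate values of a stronger neighbouring peak were carried onto a shoulder stays open. In 71.4% of the 294 the summed signal of the overlapping replicate peaks was over 5 times the pooled signal, but peaks picked for a low pooled signal have a high ratio whatever the cause, so that share decides nothing. No biological explanation was tested.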
